A study of Mus musculus with 5 samples.

How the data were processed

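RNA was sequenced from primary mouse astrocyte cultures of the C57BL/6 strain, prepared from newborn pups. Cultures were left untreated (Control, 2 libraries), given amyloid-β peptide at 1 µM (Aβ, 2 libraries), or given 1 µM Aβ with 50 µM DFMO (Aβ+DFMO, 1 library). Per the labels' protocols, treatment began on day 7 in vitro and lasted 5 days, the cells were harvested on day 12 in vitro, RNA was enriched for polyadenylated transcripts on oligo-binding beads, and cDNA libraries were sequenced as read pairs. DFMO (difluoromethylornithine) is an irreversible inhibitor of ornithine decarboxylase, the enzyme encoded by Odc1. The labels do not say whether libraries of a group came from separate cultures. The p-values therefore reflect only a spread modelled from these libraries, which may be technical.

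The submitters' processing notes name STAR 2.7.3a (a read aligner), Partek, DESeq2 and FastQC, and both the mm10 and GRCm39 mouse builds, with no role for each. The counting program, gene annotation and low-value filter are not given in the sources used here. Values per gene were used only as group means, so nothing was re-tested: the p-values and adjusted p-values are the authors', from their deposited DESeq2 table of 18783 genes, which compares Aβ with Control and Aβ+DFMO with Aβ. No test of Aβ+DFMO against Control was used, and that comparison is described only by log2 ratios of the group means. The group means are taken here as a normalized signal. The file headers call them least-squares means of each group and name no scaling. The deposited ratio and log2 ratio were checked to be the ratio of these means, and the deposited adjusted p-values to be Benjamini-Hochberg values over all 18783 genes. The deposited pathway table gives, per the file headers, a p-value and a ratio for each of 242 gene sets. A further deposited file gives the reads of each library and the percent of them that lie in exons, introns and between genes, per the file headers. Another gives the range and quartiles of each library's normalized signal, per the file headers; 2 columns of that file were not used. The design fixed before the data were examined had planned edgeR on counts per library, and it named the authors' table as the fallback that was used here.

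Depth differed greatly. The Control libraries had 49676004 and 49020833 reads, the Aβ libraries 46886111 and 105544237, and the Aβ+DFMO library 4825677, which is 9.72 to 21.9 times fewer than the others. Of the 7242 genes of the Aβ+DFMO column below 27 reads' worth, 80.2% were whole multiples, within 0.05 of a read, of 7.45 normalized units, taken here as the worth of 1 read. Dividing by it gave an estimate of the reads behind each gene, whose median was 55.8, and 5199 genes (27.7%) had fewer than 10. Too few values were whole to recover counts, so no count test was run.

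A gene was called changed at an adjusted p under 0.05 in the authors' table. A standard error was computed for each log2 ratio as its size divided by the normal deviate of the two-sided p, assuming a Wald test, and is named the implied standard error. For the 1144 genes with an Aβ mean over 5000, the implied variance of Aβ+DFMO against Aβ was 1.75 times that of Aβ against Control in the median, where 1.5 follows from the numbers of libraries alone: the lone Aβ+DFMO library was thus treated by the authors' model as varying like the other groups. Only 1.72% of the p-values for Aβ against Control were under 0.05 and 76.6% were over 0.5. These p-values lie higher than an even spread from 0 to 1 would give. The authors' model may thus assume more spread than these libraries had, and the implied standard errors may be too large. A gene that was not called is therefore not shown to be unchanged.

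For 31 gene lists fixed before the data were examined, the number of called members is given over all genes and adjusted over the list alone, together with the list's median log2 ratio and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was taken to stand apart when its median fell outside the middle 95% of the random lists. The 31 lists cover the urea cycle and ornithine, polyamines, putrescine to GABA, pan-reactive, A1 and A2 astrocytes, astrocyte identity, interferon, cytokines, complement, antigen presentation, markers of microglia, oligodendrocytes, neurons, endothelium, fibroblasts and ependyma, cell cycle, matrix, autophagy, lysosome, cholesterol, lipids, unfolded protein response, oxidative stress, glycolysis, oxidative phosphorylation, ribosomal proteins, immediate early genes, amyloid processing and mitochondrially encoded mRNAs. Named genes followed a rule fixed at the same time: up to 8 called genes with the largest rise and 8 with the largest fall at a mean of at least 1 in 1e+06 of the summed signal, without unnamed predicted genes and pseudogenes; up to 4 members with the smallest p of each list that stood apart and at most 1 of each other list; and a fixed set around Odc1, the urea cycle and astrocyte reactivity. The part of the rule that needs values per library could not be applied. Otc and Cps1 of that set, both urea cycle enzymes, were not among the 18783 genes and so could not be analysed. A gene named by the rule for a single comparison is also followed in the other where that comparison is described. Genes outside the rule are named only where said. Some genes that the rule names are not reported here.

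To test whether Aβ genes lay back towards Control in Aβ+DFMO, the share with opposite signs in the 2 comparisons was set against 100 simulated data sets in which Aβ+DFMO equals Aβ, built from the implied standard errors, since both comparisons share the Aβ libraries. Simulated errors were added to the observed log2 ratios of Aβ against Control, so each data set called more genes than observed. As many called genes as observed were therefore drawn at random from each data set, a step added after the data were seen, and those past the largest p that passed in the authors' table for Aβ+DFMO against Aβ were counted, without and with the observed GC trend added.

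GC content and length were taken from the longest transcript of each gene in GENCODE M21 (GRCm38), protein-coding transcripts first, for 18459 genes (98.3%) matched by symbol. Coordinates printed are those of that annotation. After the data were seen, a lowess trend (span 0.3) of the log2 ratio on GC content, fitted to genes with an Aβ mean of at least 200, was subtracted, and p-values were recomputed from the implied standard errors with Benjamini-Hochberg adjustment; random lists matched on expression and GC content (10 bins each) were also drawn. Tested on simulated data for Aβ+DFMO against Aβ with the observed trend and 200 of 11660 genes changed by 1.5 on the log2 scale, this correction lowered the calls among unchanged genes from 1474 to 10 and called 193 of the 200 changed genes. The simulated trend and errors had the form that the correction assumes. The simulation therefore tested neither a GC bias of another form nor changes smaller than 1.5. With log2 ratios shuffled within expression bins, 2 of the 31 lists fell outside the middle 95% for Aβ against Control and 1 for Aβ+DFMO against Aβ. After a shift of 0.5, 31 and 29 lists were found. Shuffling removes any joint variation of the members of a list, so the effect of such variation was not tested. In a simulation of the opposed share with Aβ+DFMO set to equal Control, 98.4% of the called genes were opposed. The split of the opposed share by direction and its restriction to genes with an absolute log2 ratio under 1 were also chosen after the data were seen. Other alternatives changed the threshold or left out low genes or ribosomal, repeat and small RNA features. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.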

Results

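The series measured mRNA in primary mouse astrocyte cultures to ask how Aβ alters these cells and how inhibition of ornithine decarboxylase (ODC1) with DFMO alters Aβ-treated cells. There were 2 Control, 2 Aβ and 1 Aβ+DFMO libraries, with 49020833 and 49676004 reads in Control, 46886111 and 105544237 in Aβ, and 4825677 in Aβ+DFMO. Between 84.4% and 85.2% of the reads of each library lay within exons. Values per gene are the authors' normalized group means and carry no error of their own. Each comparison with Aβ+DFMO rests on a single shallow library, and its calls assume that this library varied like those of the other groups.

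The first comparison asked what Aβ changes in these cultures. In the authors' deposited table, Mmp12, a macrophage elastase, rose from a normalized mean of 921 in Control to 3410 in Aβ (log2 ratio 1.89, implied standard error 0.105, adjusted p = 1.48e-67). Gpnmb, a glycoprotein of lysosomes in activated phagocytes, rose from 17328 to 42816 in the authors' deposited table (log2 ratio 1.31, implied standard error 0.0912, adjusted p = 1.96e-42). P2ry12, a purine receptor of resting microglia, fell by 1.37 on the log2 scale and Tmem119, another marker of that state named after its value was seen, fell by 1.33 in the authors' deposited table. Mmp12 lies on chromosome 9 at 7344381 to 7369499 on the plus strand in GRCm38, and Gpnmb on chromosome 6 at 49036546 to 49070929 on the plus strand.

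At an adjusted p under 0.05 the authors' deposited table held 54 changed genes, of which 21 were higher and 33 lower in Aβ. The other genes with the largest rises in the authors' deposited table were Fabp4 (a fatty acid carrier, log2 ratio 1.83), Atp6v0d2 (a subunit of the lysosomal proton pump, 1.81), Anpep (a surface aminopeptidase, 1.57), Rgs1 (1.48), Npy (neuropeptide Y, 1.14) and Hspa1b (a heat shock protein, 0.98). Among the largest falls in the authors' deposited table were those of the mitochondrial ribosomal RNAs mt-Rnr2 (−2.85) and mt-Rnr1, whose mean fell to 8260 in Aβ from 46812 in Control, and of the myeloid genes Gpr84 (−2.03), Slco2b1 (−1.69), Fcrls (−1.47) and Gpr34 (−1.39). Unnamed predicted genes were outside the naming rule, and CT010467.1, AY036118, Gm26917 and Gm42418 of the nuclear ribosomal RNA locus are given here after their values were seen. Of these, CT010467.1 fell by 2.02 while Gm26917 and Gm42418 rose by 0.80 and 0.61 in the authors' deposited table, and AY036118 did not pass (−1.48, unadjusted p = 0.0202). These features lie together on chromosome 17 between 39843013 and 39848827 in GRCm38, with CT010467.1 and AY036118 on the minus strand overlapping Gm42418 on the plus strand. How strand was used in counting is not given in the sources used here.

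**Figure D1:**
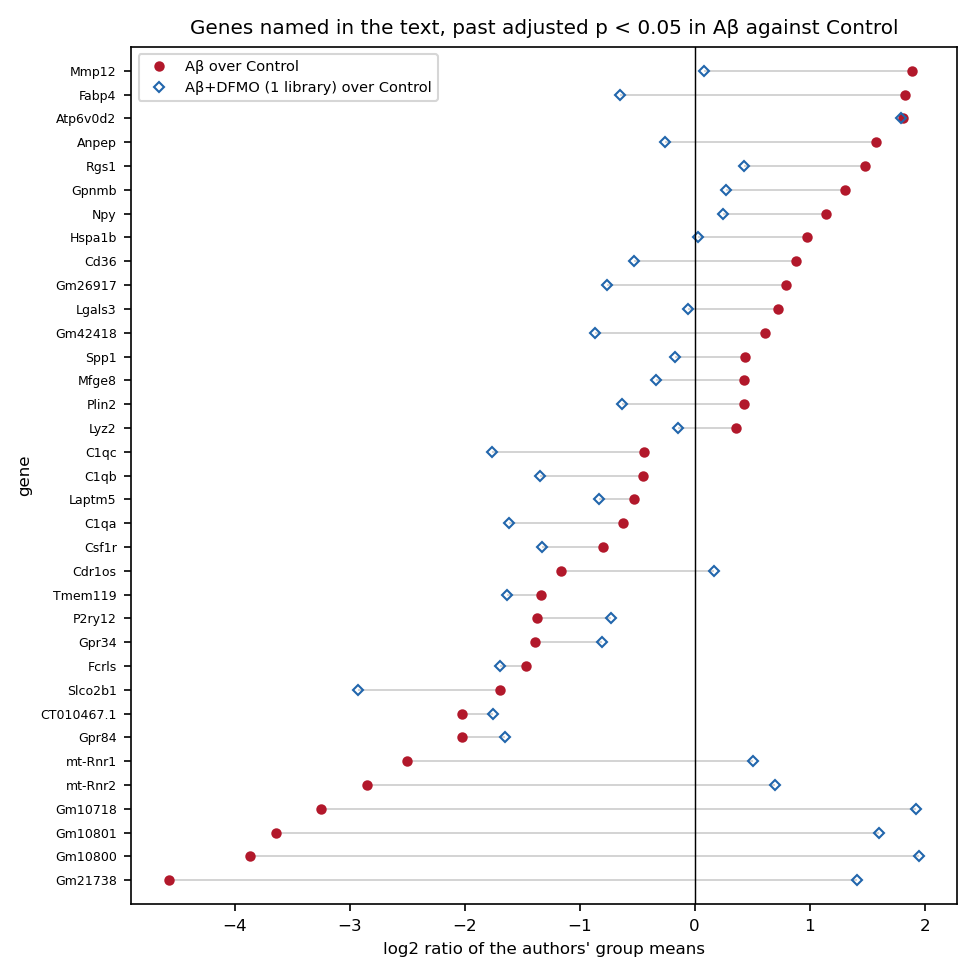
Log2 ratio over Control of the 35 genes named in the text, of the 54 past an adjusted p under 0.05 in Aβ against Control (1 line per gene, x axis in log2 units), for Aβ (filled circles) and for the single Aβ+DFMO library (open diamonds, no test). Mmp12 lies at 1.89 in Aβ and 0.08 in Aβ+DFMO, whereas C1qc lies at −0.44 and −1.76.

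Among the microglia and macrophage markers, 8 of the 21 measured members passed, 1 higher and 7 lower, and the list's median log2 ratio of −0.37 lay below that of all 10000 random lists. Adjusted over the list alone, 2 rose and 11 fell. Csf1r, the growth factor receptor that microglia depend on, fell by 0.80 and Laptm5 by 0.53, whereas Lyz2, the lysozyme of macrophages, rose by 0.36 in the authors' deposited table. Of the complement list, 4 of 15 members fell, also over the list alone, and the median of −0.06 lay at percentile 0.70. C1qa, C1qb and C1qc, the chains of the initiating C1q complex, fell by 0.62, 0.45 and 0.44 in the authors' deposited table. C1qa, C1qb and C1qc are in both lists, and the adjusted p of C1qb was 0.0496.

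Lysosomal genes lay higher as a group: the median over 29 genes was 0.10, above all 10000 random lists, although only Atp6v0d2 passed, and 3 members rose when adjusted over the list alone. The next by p-value were the cathepsins Ctsl (0.30), Ctsd (0.20) and Ctsb (0.16), which did not pass over all genes in the authors' deposited table. Of 26 genes of lipid transport and fatty acid metabolism, 2 rose (3 when adjusted over the list alone), with a list median of 0.04 at percentile 98.7. They were Cd36, a scavenger receptor that takes up lipids (log2 ratio 0.88), and Plin2, which coats lipid droplets (0.43), in the authors' deposited table. Next by p-value there were Fabp5 (0.34), which passed over the list alone but not over all genes, and Apoe (−0.11), which passed neither way. Spp1 (osteopontin, 0.44) was the single member of the cytokine list to pass and Mfge8 (a bridge for phagocytosis, 0.43) that of the astrocyte identity list in the authors' deposited table. Lgals3 (galectin-3, 0.73 in the authors' deposited table), outside the rule and named after its value was seen, also rose.

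Medians of a further 6 lists lay outside the middle 95% of random lists by small amounts. The A1 astrocyte list lay lower (median −0.13, percentile 0.07) and so did the interferon response (−0.06, percentile 1.25). Extracellular matrix (0.05, percentile 99.8), oxidative stress response (0.06, percentile 99.95), oxidative phosphorylation (0.04, percentile 99.65) and ribosomal proteins (0.04, percentile 99.9) lay higher. None of these 6 lists had a member past an adjusted p under 0.05 over all genes in the authors' DESeq2 table; adjusted over the list alone, 3 genes of the oxidative stress response rose and no member of the other 5 passed. Members with the smallest p-values in the authors' deposited table were Serping1 (−0.19), Ggta1 (−0.14), Srgn (−0.30) and Fkbp5 (−0.18) of the A1 list and Ifit2 (−0.08), Zbp1 (−0.78), Bst2 (−0.13) and Rsad2 (0.29) of the interferon response. In the authors' deposited table they were Col4a2 (0.22), Col4a1 (0.19), Lama2 (0.37) and Tnc (0.19) of the matrix list and Hmox1 (0.36), Slc7a11 (0.54), Ftl1 (0.22) and Srxn1 (0.25) of the oxidative stress response. For oxidative phosphorylation and ribosomal proteins the authors' deposited table gave Atp5o (0.09), Uqcrc2 (0.07), Ndufa1 (0.12) and Cox5b (0.09), and Rpl37 (0.29), Rps6 (0.15), Rps24 (0.09) and Rpl11 (0.20). In all, 10 of 31 lists lay outside, where about 1.55 would do so by chance if the members of a list varied independently. Genes of a cell type or pathway can vary together between libraries without a treatment effect, and some lists share genes. More lists than that could therefore lie outside by chance.

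Neither polyamine and urea cycle enzymes nor markers of reactive astrocytes passed in Aβ. No member of the 12 measured urea cycle and ornithine genes, the 18 polyamine genes, the 13 genes of putrescine to GABA or the 13 pan-reactive astrocyte genes was called by the authors' DESeq2 test, and their medians were −0.01, 0.02, −0.03 and −0.04, at percentiles 34.4, 78.7, 12.3 and 4.88. Against random lists matched on GC content as well, the pan-reactive median lay outside the middle 95%, at percentile 2.25, and the other 3 stayed inside. Adjusted over the list alone, 1 urea cycle and ornithine gene fell, Gatm (−0.39 in the authors' deposited table), which makes the precursor of creatine, and no member of the other 3 lists passed. At an unadjusted p under 0.05 the whole table held 324 genes, and Atp13a3 (−0.22), Abat (0.07) and Cd44 (−0.20) had the smallest p-values of those 3 lists in the authors' deposited table. Odc1, which lies on chromosome 12 at 17544794 to 17551505 on the plus strand in GRCm38, had a mean of 8744 in Control and 9293 in Aβ in the authors' deposited table, a log2 ratio of 0.09 with an implied standard error of 0.080. In the authors' deposited table, the log2 ratio was 0.01 for Gfap and 0.05 for Vim, the intermediate filaments of astrocytes, 0.23 for Lcn2 (lipocalin-2), −0.15 for Serpina3n (an acute-phase protease inhibitor), 0.04 for the water channel Aqp4 and −0.05 for Maob, which oxidises monoamines and acetylputrescine. Urea cycle genes had log2 ratios in the authors' deposited table of 0.21 for Ass1, 0.03 for Asl and −0.34 for Arg1, the last at a mean of only 10.2 in Control. For Amd1, Srm, Sms and Sat1, enzymes of polyamine synthesis and acetylation, the authors' deposited table gave 0.02, −0.02, −0.12 and −0.03. Large spreads limit the low genes: the implied standard error was 1.04 for Arg1 and 0.217 for Maob.

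The remaining lists did not stand apart in Aβ against random lists matched on expression. Medians were −0.01 for A2 astrocyte genes, 0.01 for astrocyte identity, 0.03 for cytokines, −0.02 for antigen presentation, 0.01 for oligodendrocyte lineage markers, −0.01 for neuron markers, 0.07 for endothelial markers, 0.02 for fibroblast, meningeal and mural markers, 0.05 for ependymal markers, 0.02 for cell cycle, 0.01 for autophagy, −0.02 for cholesterol synthesis, 0.02 for the unfolded protein response, 0.02 for glycolysis, −0.03 for immediate early genes, 0.03 for amyloid processing and 0.02 for mitochondrially encoded mRNAs. When GC content was matched too, the last of these lay above the middle 95%, at percentile 99.3 in place of 69.8. The other 16 stayed inside. Apart from Mfge8 and Spp1, no member of these 17 lists passed over all genes in the authors' DESeq2 table. Adjusted over the list alone, Postn (−0.27) of the fibroblast list and Slc7a11 of the unfolded protein response also passed in the authors' deposited table. The members with the smallest p-values of the other 13 lists in the authors' deposited table were Ptgs2 (0.33), H2-Q4 (−0.15), Cnp (−0.15), Gap43 (−0.20), Esam (0.68), Ttr (−1.44), Pcna (0.09), Sqstm1 (0.10), Hmgcs1 (−0.11), Gapdh (0.12), Klf6 (−0.12), Apoe and mt-Co1 (0.13). The authors' deposited pathway table had 43 gene sets past an adjusted p under 0.05 in Aβ against Control, 10 with a ratio over 1 and 33 under 1, led by Fc gamma R-mediated phagocytosis (ratio 0.984, adjusted p = 1.87e-08). The test behind these p-values is not given in the sources used here. They may treat the genes of a set as replicates, so they need not measure the spread between libraries.

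The question of the second comparison was what DFMO changes in Aβ-treated cultures. Polyamine genes moved in both directions in the single Aβ+DFMO library. In the authors' deposited table, Odc1 was higher in Aβ+DFMO than in Aβ, at 12235 against 9293 (log2 ratio 0.40, implied standard error 0.104, adjusted p = 0.00415). Amd1, which makes the aminopropyl donor for spermidine and spermine, rose by 0.91, and Azin1, an inhibitor of the antizymes that degrade ODC1, by 0.61 in the authors' deposited table. Smox, which oxidises spermine, fell by 1.16, and the antizymes Oaz1 and Oaz2 by 0.56 and 0.47 in the authors' deposited table. DFMO acts on the ODC1 protein, so the level of its transcript is no check of the treatment.

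Of the 18 polyamine genes, 5 rose and 4 fell, and 5 and 5 when adjusted over the list alone; the median of −0.20 lay at percentile 2.74, inside the middle 95%. The others that passed in the authors' deposited table were the transporter genes Atp13a3 (0.52) and Atp13a2 (−1.10), and Mtap (0.44). Azin1, Smox, Oaz1, Oaz2, Atp13a2, Atp13a3 and Mtap are named here after their values were seen. Sat1 (−0.14), Srm (−0.27) and Sms (0.32) did not pass in the authors' deposited table. After a trend with GC content, described next, was taken out, 3 polyamine genes still passed: Odc1 (0.54, adjusted p = 7.01e-05), Amd1 (0.62, adjusted p = 0.000162) and Smox (−0.91, adjusted p = 0.0341).

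In the authors' deposited table, 1724 genes passed in Aβ+DFMO against Aβ, 751 higher and 973 lower. The log2 ratio followed the GC content of the transcript: across 11660 genes with an Aβ mean of at least 200, which are not independent replicates, Spearman's rho was −0.71 and Pearson's r −0.68, against 0.12 and 0.09 for Aβ against Control. In the 1166 of these genes with the lowest GC content the median log2 ratio was 0.34, with 337 genes higher and 7 lower, and in the 1166 with the highest it was −0.53, with 1 gene higher and 392 lower. Taking out the trend, an analysis chosen after seeing the data, left 288 genes, 153 higher and 135 lower, of which 208 had been called before in the same direction, and 100 of the 1703 earlier calls with a GC value turned sign.

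**Figure D2:**
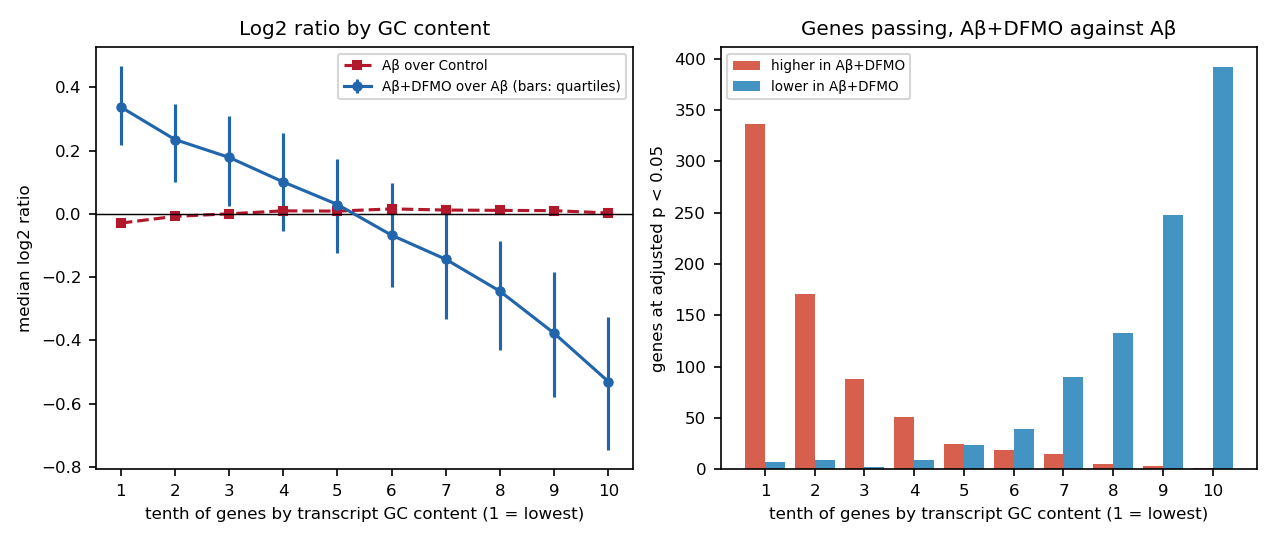
Left, median log2 ratio (y axis) in 10 groups of 1166 genes ordered by transcript GC content (x axis) for Aβ+DFMO over Aβ (circles, bars from the lower to the upper quartile) and Aβ over Control (squares); right, number of genes past an adjusted p under 0.05 in Aβ+DFMO against Aβ in each group, by direction. The median falls from 0.34 to −0.53 for Aβ+DFMO over Aβ, and lies between −0.03 and 0.02 for Aβ over Control.

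Under the naming rule, which leaves out unnamed predicted genes, the largest rises in Aβ+DFMO in the authors' deposited table were those of mt-Rnr2 (3.55) and mt-Rnr1 (3.01), followed by Zfp965 (2.15), the histone gene H3c14 (1.78), the smooth muscle myosin Myh11 (1.37), Cdr1os (1.34), Depdc1a (1.28) and Pwwp3b (1.21). The largest falls under that rule in the authors' deposited table were those of the chemokine Ccl9 (−2.74), Selplg (−2.58), Glcci1 (−2.54), Ebf4 (−2.33), Ctla2b (−2.11), Htra3 (−2.03), Dmrtb1 (−1.99) and Efna4 (−1.91). All 8 falls rested on an estimated 3 to 6 reads in the Aβ+DFMO library, and with the GC trend taken out only Ccl9 of them passed (−3.00, adjusted p = 0.0125). Glcci1 (−2.65, adjusted p = 0.0671) and Ctla2b (−2.35, adjusted p = 0.0675) then lay lower than before without passing. The other 5 lay between −2.11 and −1.47. Of the rises, mt-Rnr2, mt-Rnr1, Zfp965 and Myh11 passed again, Depdc1a did not (0.80, adjusted p = 0.120), and H3c14, Cdr1os and Pwwp3b had no GC value.

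Genes of glial cell types were lower in this library. Of the 16 oligodendrocyte lineage markers 12 fell (13 when adjusted over the list alone), and their median of −1.05 lay below all 10000 random lists, also below all those matched on GC content. Log2 ratios in the authors' deposited table were −1.57 for Mbp (myelin basic protein), −1.82 for Sox10, −0.90 for Olig1 and −0.71 for Cnp, all past the threshold; with the GC trend taken out, Mbp (−1.50) and Sox10 (−1.20) passed and Olig1 (−0.32) and Cnp (−0.38) did not, and 5 members passed in all. Of 25 genes of astrocyte identity and homeostasis 12 fell (16 when adjusted over the list alone), with a median of −0.34 below all random lists of both kinds, and 10 were lower with the GC trend taken out. Aldoc fell by 0.99, the lipoprotein gene Apoe by 0.91 and Hepacam by 0.70 in the authors' deposited table, and these 3 passed again, at −0.87, −0.40 and −0.51. Aqp4 did not differ past the threshold (0.04 in the authors' deposited table; −0.24, adjusted p = 0.433, with the GC trend taken out).

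Of the 13 pan-reactive astrocyte genes 4 fell, with a median of −0.33 at percentile 0.47, and 4 fell when adjusted over the list alone. Serpina3n fell by 0.90, S1pr3 by 0.57, Lcn2 by 0.58 and Gfap by 0.47 in the authors' deposited table. With the GC trend taken out, Serpina3n (−0.78) and S1pr3 (−0.47) passed, whereas Gfap (−0.17, adjusted p = 0.765) and Lcn2 (−0.36, adjusted p = 0.573) no longer did, their log2 ratios having moved towards 0 at implied standard errors of 0.108 and 0.186. Vim (−0.16) did not pass in the authors' deposited table. The A1 list had 3 members lower, also over the list alone, led by Serping1 (−0.58 in the authors' deposited table), and a median of 0.04 at percentile 66.3. The A2 list had 2 higher and 1 lower (3 and 1 over the list alone), led by B3gnt5 (0.56 in the authors' deposited table), and a median of −0.08 at percentile 25.1. These A1 and A2 calls were all lost once the GC trend was taken out, with Serping1 at −0.44 (adjusted p = 0.254) and B3gnt5 at 0.19 (adjusted p = 0.847).

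Complement genes fell in 8 of 15 cases (9 over the list alone), with a median of −0.63 below all random lists of both kinds, and microglia and macrophage markers in 8 of 21 (9 over the list alone), with a median of −0.48 below all random lists matched on expression. C1qc fell by 1.32, C1qa by 0.99, C1qb by 0.90, C3ar1 by 0.63, Cd68 by 1.01 and Lyz2 by 0.51 in the authors' deposited table. With the GC trend taken out 3 complement genes and 4 microglia and macrophage markers passed, among them C1qc, C3ar1, Cd68 and Lyz2 but neither C1qa nor C1qb. Oxidative stress genes fell in 11 of 24 cases (13 over the list alone; median −0.41, below all random lists), among them the ferritin gene Ftl1 (−1.32), Gpx4 (−1.30), Mt2 (−0.71) and Mt1 (−0.58) in the authors' deposited table, and 5 were lower with the GC trend taken out. Lipid genes fell in 6 of 26 cases (7 over the list alone; median −0.27, percentile 0.12), and also 6 with the GC trend taken out. Cd36 (−1.41), Plin2 (−1.06) and Scd2 (−0.50) in the authors' deposited table were among them.

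Other lists stood apart in the authors' values as follows. Cholesterol synthesis (4 of 23 lower, 5 over the list alone, median −0.29, percentile 0.09), amyloid processing (4 of 20 lower and 1 higher, 5 and 1 over the list alone, median −0.24, percentile 0.15), lysosome (6 of 29 lower, 9 over the list alone, median −0.19, percentile 0.32) and glycolysis (7 of 24 lower and 1 higher, 9 and 2 over the list alone, median −0.22, percentile 0.37) lay lower. Cell cycle genes (7 of 30 higher, 9 over the list alone, median 0.23, percentile 99.9) and mitochondrially encoded mRNAs (7 of 9 higher, also over the list alone, median 0.36, percentile 99.7) lay higher. Falls in the authors' deposited table included those of Srebf2 (−0.57), Tm7sf2 (−1.17) and Fdps (−0.50) in cholesterol synthesis, Aplp1 (−0.92) and Mapt (−0.98) in amyloid processing, Ctsd (−0.71), Grn (−0.61), Ctsb (−0.46) and Psap (−0.45) in the lysosome, and Aldoa (−0.62), Eno1 (−0.49), Pkm (−0.36) and Hk1 (−0.46) in glycolysis. Rises in the authors' deposited table were those of Mme, the amyloid-degrading neprilysin (0.69), the mitotic genes Cenpe (0.71), Ccna2 (0.47), Kif11 (0.57) and Bub1 (0.68), and mt-Co2 (0.62), mt-Nd2 (0.55), mt-Co3 (0.40) and mt-Co1 (0.46). With the GC trend taken out, 2 lysosomal genes (Ctsb and Ctsd) and 2 amyloid processing genes (Apoe and Mapt) passed, all 4 lower, and no member of the cholesterol, glycolysis, cell cycle or mitochondrial lists did; 3931 genes of the authors' DESeq2 table had an unadjusted p under 0.05 before it. Mme (0.29, adjusted p = 0.328) and Aplp1 (−0.37, adjusted p = 0.655) then no longer passed. Against random lists matched on GC content, the lysosome (percentile 3.84), glycolysis (22.1) and mitochondrial (69.8) medians were inside the middle 95%, while cell cycle (above all 10000) and cholesterol synthesis (0.08) stayed outside. The same matching placed 3 further lists below the middle 95%, putrescine to GABA (percentile 1.24), cytokines (2.19) and neuron markers (2.23), and 2 above it, extracellular matrix (99.4) and ribosomal proteins (above all 10000).

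Among 12 urea cycle and ornithine genes only Glul, glutamine synthetase, passed (−0.42 in the authors' deposited table), also over the list alone, with a list median of −0.07 at percentile 24.2. Ass1 (−0.09), Asl (−0.33) and Arg1 (−0.11, about 1 read in Aβ+DFMO) did not pass in the authors' deposited table. Of the 13 genes of putrescine to GABA, 2 fell, also over the list alone, Aldh2 (−0.72) and Aldh7a1 (−0.43, named after its value was seen) in the authors' deposited table, with a list median of −0.23 inside the middle 95% of random lists matched on expression. Both calls were lost once the GC trend was taken out, at −0.46 (adjusted p = 0.126) and −0.39 (adjusted p = 0.112). Maob (−0.15 in the authors' deposited table, 28.0 estimated reads) did not pass.

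The remaining lists lay inside the middle 95% when matched on expression. Medians were 0.10 for the interferon response, −0.20 for cytokines, −0.10 for antigen presentation, −0.28 for neuron markers, 0.21 for endothelial markers, −0.13 for fibroblast, meningeal and mural markers, −0.15 for ependymal markers, 0.01 for extracellular matrix, −0.05 for autophagy, −0.12 for the unfolded protein response, −0.05 for oxidative phosphorylation, 0.08 for ribosomal proteins and −0.18 for immediate early genes. In that order, called members numbered 0 higher and 1 lower, 0 and 1, 1 and 3, 1 and 3, 1 and 0, 3 and 1, 0 and 1, 4 and 2, 1 and 4, 3 and 2, 1 and 2, 3 and 8, and 1 and 2. Adjusted over the list alone they differed for antigen presentation (1 and 5), matrix (6 and 2), autophagy (1 and 5), the unfolded protein response (3 and 3) and ribosomal proteins (6 and 8). The smallest p-values in the authors' deposited table were, in the same order, those of Bst2 (−1.08), Spp1 (−0.61), B2m (0.36), Stmn2 (0.57), Slco1a4 (0.33), Postn (0.45), Foxj1 (−0.93), Lox (0.88), Rb1cc1 (0.52), Hsp90b1 (0.43), Uqcrb (0.57), Rplp1 (−0.74) and Jund (−0.92). Of these 13 genes, Spp1 (−0.83), Stmn2 (0.44) and Lox (0.67) passed again once the GC trend was taken out, and the other 10 lay nearer 0 without passing. Called members then numbered 1 higher and 1 lower for cytokines, 1 and 1 for neuron markers, 4 and 0 for fibroblast, meningeal and mural markers, 7 and 0 for matrix, and 2 and 1 for ribosomal proteins. The other 8 of these lists had 0. In the authors' deposited pathway table, 171 sets passed in Aβ+DFMO against Aβ, 57 with a ratio over 1 and 114 under 1. The smallest adjusted p was that of Fc gamma R-mediated phagocytosis (ratio 0.988, adjusted p = 2.15e-38), followed by arginine and proline metabolism (ratio 0.806, adjusted p = 7.96e-24). The GC trend was not taken out of these values. Some sets that passed lay far from 1, such as ribosome biogenesis in eukaryotes (ratio 3.58). Since a ratio of 0.988 also passed with 1 Aβ+DFMO library, such p-values may treat the genes of a set as replicates. They are not evidence of a treatment effect.

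**Figure D3:**
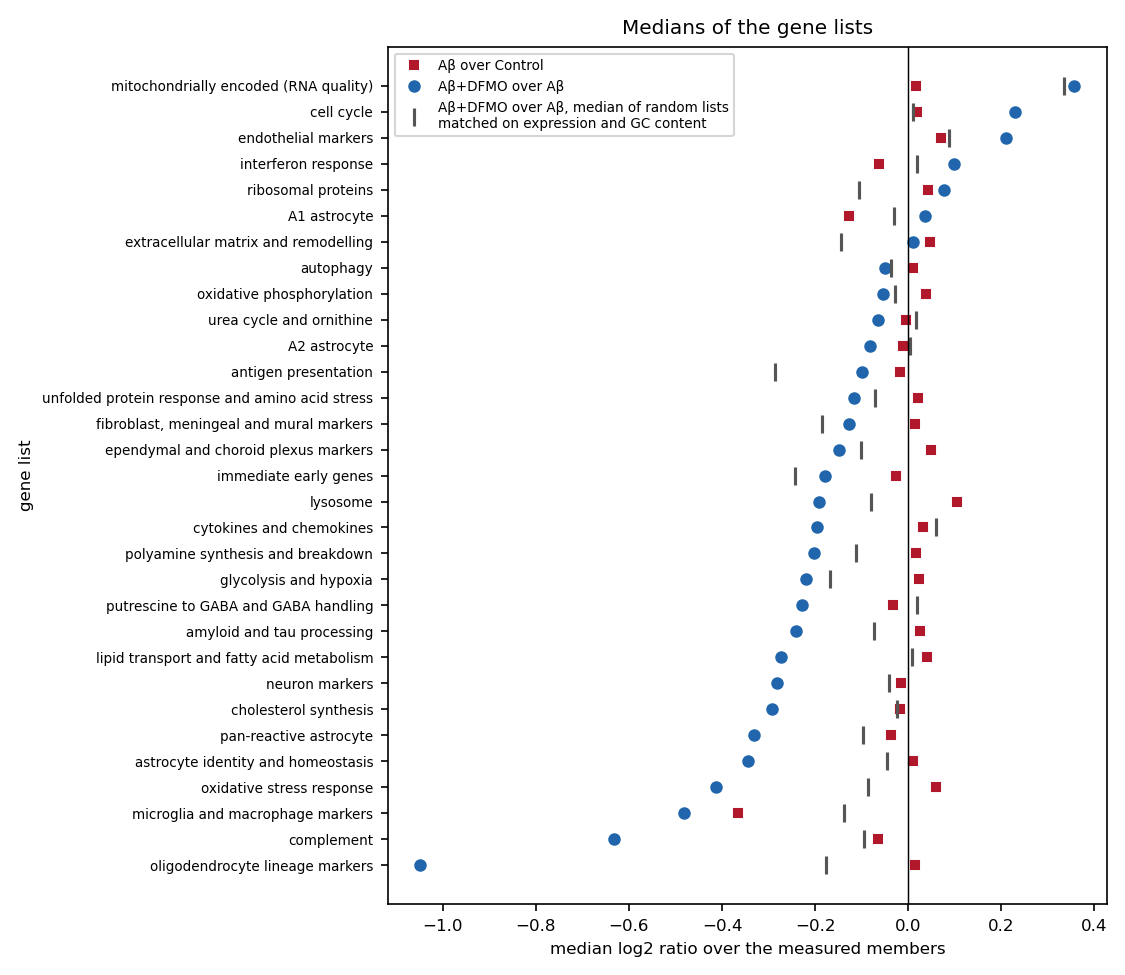
Median log2 ratio (x axis) over the measured members of each of 31 gene lists (rows) for Aβ over Control (squares) and Aβ+DFMO over Aβ (circles), with the median of random lists matched on expression and GC content for Aβ+DFMO over Aβ (bars). Oligodendrocyte lineage markers lie at −1.05 in Aβ+DFMO over Aβ and 0.01 in Aβ over Control.

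The last comparisons asked whether genes changed by Aβ lay back towards Control in Aβ+DFMO. Of the 21 genes that Aβ raised, 20 were lower in Aβ+DFMO than in Aβ, and 12 of them passed in that direction in the authors' table, 2 of these being ribosomal, repeat or small RNA features. Draws of 21 raised genes from simulated data sets in which Aβ+DFMO equals Aβ, with the error of the Aβ libraries shared, gave 0 to 2 genes past it in that direction, and 0 to 7 when the observed GC trend was added. Mmp12, Gpnmb, Anpep, Cd36, Lgals3, Spp1, Plin2, Mfge8 and Lyz2 fell by 1.80, 1.04, 1.83, 1.41, 0.79, 0.61, 1.06, 0.77 and 0.51 on the log2 scale in the authors' deposited table, and with the GC trend taken out all of these 9 except Mfge8 (−0.35, adjusted p = 0.281) passed again. Atp6v0d2 stayed at 417 against 423 in Aβ in the authors' deposited table. The microglia and macrophage markers, which include Lyz2, were lower in this library as a list. Only 2 of the 21 lay above 0, and their median was −0.48 (−0.29 with the GC trend taken out). A fall of raised genes thus cannot by itself tell a return towards Control from a lower level of such genes in this library. Among the 33 genes that Aβ lowered, 17 were above Aβ in Aβ+DFMO, 8 of them past the threshold. Draws of 33 lowered genes gave 0 to 2 such genes and, with the GC trend added, 1 to 8. Of the 8 observed, 7 were ribosomal, repeat or small RNA features and the other was Cdr1os. Without such features 9 of 25 lowered genes lay above Aβ. A further 6 lowered genes fell again past the threshold. Draws gave 0 to 1 of these and, with the GC trend added, 0 to 3. Of the 6, only C1qc (−0.90) passed with the GC trend taken out, the other 5 then lying nearer 0. Fcrls (−0.22), Slco2b1 (−1.24), Tmem119 (−0.30), Csf1r (−0.53) and C1qa (−0.99) lay further below Control still in the authors' deposited table, C1qa past the threshold and Slco2b1 and Tmem119 on an estimated 3 and 9 reads, whereas P2ry12 (0.65) and Gpr34 (0.58) lay above Aβ without passing. C1qa no longer passed once the GC trend was taken out (−0.48, adjusted p = 0.302), and Tmem119 then turned sign (0.19) without passing.

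In all, 37 of the 54 genes (68.5%) were opposed, which was inside the range of 48.1% to 81.5% from draws of 54 called genes, 1 draw from each of 100 simulated data sets in which Aβ+DFMO equals Aβ. Split by direction after the data were seen, the share was 95.2% for the 21 genes raised by Aβ, above the range of 47.6% to 90.5% from draws of 21. It was 51.5% for the 33 genes lowered by Aβ, inside the range of 45.5% to 81.8% from draws of 33. These simulated shares left out the GC trend and treated genes as varying independently, which genes of the same cells need not do. With the GC trend taken out of the observed values, all 21 raised genes were lower in Aβ+DFMO than in Aβ. Across 11780 genes with an Aβ mean of at least 200 the covariance of the 2 log2 ratios was −0.0045, nearer 0 than the simulated −0.0103 (range −0.012 to −0.0090), and Pearson's r was −0.10. The simulated shares rest on the same implied standard errors, and each simulated data set called 101 to 170 genes, more than the 54 observed. In the covariance and in the number of calls the simulations thus did not match the data. All ranges from these draws are a rough guide only, and a share inside or above its range does not settle the question. The Aβ libraries could not be split, so their error enters both comparisons with opposite sign.

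Against Control, Aβ+DFMO has no test. Log2 ratios of the group means from the authors' values were 0.08 for Mmp12, 0.27 for Gpnmb, 0.48 for Odc1 and 0.92 for Amd1. Other genes raised by Aβ lay on both sides of Control, among them Plin2 (−0.64), Cd36 (−0.53), Anpep (−0.26) and Atp6v0d2 (1.79). The list medians were −0.95 for oligodendrocyte lineage markers, −0.84 for microglia and macrophage markers, −0.63 for complement and −0.34 for astrocyte identity, each below all random lists matched on expression, and 14 of 31 lists lay outside the middle 95%. With GC content matched as well, lysosome (percentile 18.7), glycolysis (19.4), amyloid processing (12.7) and mitochondrially encoded mRNAs (96.1) no longer did, and extracellular matrix (99.9) and ribosomal proteins (99.7) did. The log2 ratio followed GC content here too, with Spearman's rho of −0.68 across the 11660 genes.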

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

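The tests of GC content on the polyamine, oligodendrocyte lineage and mitochondrial genes were set before the GC-adjusted values were seen; those of GC content and length over all genes, of GC content on the microglial genes, of the lone library, of lower shares of microglia and of oligodendrocyte lineage cells, and all 3 on ribosomal RNA were chosen only after the result was seen. The percent of reads within introns, which no comparison used, was above both Control libraries (3.29% and 3.53%) in the Aβ library of 105544237 reads, at 3.88%, and in the Aβ+DFMO library, at 3.83%. The other Aβ library, at 3.22%, was below both Control libraries.

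The 1724 calls in Aβ+DFMO against Aβ were sorted by GC content. Spearman's rho between log2 ratio and transcript length was 0.063 across genes, which argues against length, whereas the rho with GC content was −0.71 and is consistent with a GC bias of this library as a source of much of the count. GC content as the whole source is argued against by the 3 polyamine genes that passed with its trend taken out and by the oligodendrocyte lineage median, at percentile 0 of random lists matched on expression and GC content, while the rise of the mitochondrially encoded mRNAs could come from it, as 0 of them still passed. A lower share of oligodendrocyte lineage cells, whose markers Olig1 and Mbp had means of 17044 and 4374 in Aβ, stays open: for 25% of the 16 markers (4) the implied 95% interval left out their common GC-adjusted median, at the bound set. With 1 Aβ+DFMO library, an effect of DFMO and a difference of this culture, preparation or sequencing run cannot be told apart.

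Microglial genes moved apart in Aβ. A lower share of microglia alone would lower their markers alike, but for 61.9% of them (13 of 21) the implied 95% interval left out the list's median, 8 of these lying above it, with Lyz2 up by 0.36 from a Control mean of 25844 and Csf1r down from 2463 to 1418. GC content is argued against as well, as its trend gave at most 2.47% of the log2 ratio of any of the 8 called members. A candidate explanation that remains is a change of state of microglia in these astrocyte cultures under Aβ, possibly with some loss of cells, as 3 members are also complement genes and no sort removing microglia is given in the labels. A difference between the cultures unrelated to Aβ stays open with 2 libraries per group.

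Of 12 ribosomal, repeat and small RNA features, gathered after their values were seen, 10 passed in Aβ against Control. Less mitochondrial RNA is argued against by the median log2 ratio of 0.017 of the mitochondrially encoded mRNAs. Of the 3 called features of the nuclear ribosomal RNA locus, 2 rose while CT010467.1 fell, so these features did not share a single factor. The 2 that rose are annotated as long non-coding RNA, however. The called features annotated as ribosomal RNA, CT010467.1 (−2.02), mt-Rnr2 (−2.85) and mt-Rnr1 (−2.50), all fell. A common factor of carried-over ribosomal RNA therefore stays open. Reads divided differently within the locus are argued against by its sum, which fell by 1.84 on the log2 scale, from 3.95% to 1.14% of the summed signal. The highest value of any feature was 1042210 and 1133110 in the Control libraries, whose mean matches that of CT010467.1, and 348846 and 213007 in the Aβ libraries, so neither Aβ library reached the Control level. A difference in poly(A) enrichment between preparations could also differ by RNA class, but this was not tested, and neither was a biological explanation.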

How the results depend on the processing

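The thresholds and the filter on low means were set before the data were examined; the GC, length, read-depth, ribosomal-feature and opposed-gene size and direction settings were chosen after seeing the data. With Aβ against Control, the 54 genes became 324 at an unadjusted p under 0.05, 27 with an absolute log2 ratio of at least 1 and 32 among genes at or above the median mean, and between 42 and 61 under the other 3 settings. The 1724 genes of Aβ+DFMO against Aβ became 3931 at an unadjusted p under 0.05, 203 with an absolute log2 ratio of at least 1, 288 with the GC trend taken out and 281 with the GC and length trends taken out, and between 1709 and 2398 under the other 4; the 9 polyamine genes became 2 with an absolute log2 ratio of at least 1 and 3 with the GC trend taken out. With the GC trend taken out more genes were higher (153) than lower (135), against 751 and 973 before. The opposed share of 68.5% lay between 59.3% and 77.8% under 5 other settings, each inside the range of simulated draws of its own number of genes, but was 95.2% among genes raised by Aβ, above their range, and 51.5% among genes lowered by Aβ, inside theirs. These ranges came from simulations without the GC trend, which did not match the observed covariance, and are a rough guide only. With the GC trend taken out, 47 of the 80 called genes with a GC value that the rule named for Aβ+DFMO against Aβ no longer passed, and sign turned for Pkm (0.063, 1 of the 47), Ass1 (0.18), Vim (0.062), Aqp4 (−0.24) and Srm (0.26), and for Gfap in Aβ against Control (−0.0025); none of these 6 passed after it, and the cause of each was not tested beyond the trend itself. With random lists matched on GC content, 12, 15 and 12 lists stood apart in place of 10, 13 and 14 (Aβ against Control, Aβ+DFMO against Aβ, Aβ+DFMO against Control), with 10 shared in each. In Aβ against Control the 2 added lists were the pan-reactive astrocyte and the mitochondrially encoded genes. No paired analysis was possible because the values per gene are group means. For the same reason the edgeR, limma and repeat DESeq2 fits, the other scalings, pseudocounts and count filters, the replicate block, the gene set tests, leaving out libraries, and the split of the Aβ libraries were not run. Depth limits Aβ+DFMO: 27.7% of genes had under 10 estimated reads.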

Other observations

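The GC-adjusted tests reported here were chosen only after the data were seen. With the GC trend taken out, 7 of 28 extracellular matrix genes were higher in Aβ+DFMO than in Aβ and none was lower, and the list's median lay at percentile 99.4 among random lists matched on expression and GC content, against 31.5 when matched on expression alone. Lox, which crosslinks collagen, rose by 0.67, Col5a2 by 0.54, Thbs1 by 0.53 and Col4a1 by 0.44 in GC-adjusted log2 ratios. Of 16 fibroblast, meningeal and mural markers 4 rose, among them Myl9 (0.72) and Foxc1 (0.77), but that list as a whole was not shifted, its median lying at percentile 72.4. The median of the ribosomal protein genes lay above all 10000 GC-matched lists, against percentile 79.5 when matched on expression alone. Of the 37 members, 19 lay above 0 before the GC trend was taken out. With it taken out, 2 were called higher and 1 lower. The single genes given in this paragraph were named after their values were seen.

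Among polyamine genes with the GC trend taken out, Azin1 (0.26), Oaz1 (−0.17), Oaz2 (−0.28), Atp13a3 (0.18), Atp13a2 (−0.44) and Mtap (0.31), which had passed before, kept their sign and did not pass, and Sat1 lay at −0.33 without passing.

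The 4 predicted genes Gm21738, Gm10800, Gm10801 and Gm10718 had log2 ratios from −4.57 to −3.25 in Aβ over Control and from 5.18 to 5.98 in Aβ+DFMO over Aβ in the authors' deposited table, each at a mean under 229 in Control.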
